A study of Mus musculus with 4 samples.

How the data were processed

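Single-cell RNA-seq of whole fetal mouse lung at embryonic day E18.5 gave 4 libraries, 2 labelled Control and 2 labelled PRDM3/16 KO. Per the labels' protocols, each library was made from 2 lungs of one genotype, minced, digested with enzymes, passed through a filter and treated with red cell lysis buffer before droplet capture. The deposited values are UMI counts per gene and barcode, whole numbers that were not normalised, and per the submitters' processing notes they came from Cell Ranger 6.1.2 with the mm10 build; Seurat 4.1.0 is also named there. The annotation release is not given in the sources used here. Gene symbols and identifiers were taken as deposited, and positions are those of the GENCODE annotation of the same build. The labels do not say whether control animals carried Cre, do not tie equal replicate numbers across the groups and give no sequencing batch. The library was the replicate (n = 2 per group), and the p-values of single genes and of shares by edgeR measure the spread between libraries. The p-values of gene lists with a preset correlation compare list genes with other genes. They do not measure how the shift of a list varies between libraries.

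Counting was done on the matrices as deposited. Control 1, Control 2, KO 1 and KO 2 held 17407, 2874, 5791 and 5674 barcodes. Barcodes with under 500 detected genes (2814, 821, 2857 and 2807) or over 15% mitochondrial UMIs (536, 380, 1014 and 737) were removed. Both counts are over all barcodes, and many barcodes fall in both. Doublet scores were computed per library with scrublet, and the barcodes with the highest scores, 0.8% per 1000 barcodes in the matrix, were removed (2015, 46, 132 and 126 cells, or 13.9%, 2.31%, 4.65% and 4.53%). This left 12458, 1947, 2707 and 2656 cells with a median of 2057, 4514, 3770 and 4010.5 genes. In epithelial cells the median depth was 8138, 28864, 32020 and 29689 UMIs. Counts of the 2 libraries of a group differed by far more than sampling noise, so no library was a duplicate of another.

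For clustering alone, each cell was thinned to at most 5000 UMIs. With scanpy 1.11.5 on Python 3.11.15, 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0, first over all cells and then within each compartment. Hemoglobin genes were left out of the clustering, and genes of the AT2 and airway secretory lists were left out in non-epithelial compartments. A compartment was present in a cluster where its markers had a mean log2 CPM of at least 6 and absent under 5.5, and clusters with markers of more than one compartment, or a median hemoglobin share over 10%, were kept out of the tested compartments. A cluster was named as a class, such as AT2-like, where at least 3 markers fixed beforehand were detected, at 2 times the mean of the other clusters and at least 10 CPM, with 1 or more among its 10 leading genes. A cluster in which another class reached a share of detected markers of at least 0.75 times that of the leading class was named for both and not tested. In total 5 versions of this classification were looked at, all before any differential test and after cluster tables had been seen, and the last one was used. Class names are rebuilt from markers and are not the authors' annotation.

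Raw counts, not thinned, were summed per library and class, and a class was tested where each library held at least 20 of its cells. Sums were compared with edgeR 4.0.16 on R 4.3.3, with its quasi-likelihood test, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes and of shares come from edgeR, and all values called CPM are TMM-scaled unless stated otherwise. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The difference of KO effects between AT1-like and AT2-like cells was tested as an interaction with library as a term. Gene lists, 39 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 where at least 5 genes were measured; in the comparisons made, no list was called when the correlation was estimated from the data. Counts of list members are given over all genes and adjusted over the list alone. Shares were compared with edgeR on cell numbers and with a two-sided exact permutation test, and their 95% intervals are exact binomial and cover counting error only.

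Markers, gene lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named Prdm16, Mecom and Shh first in every comparison. In the epithelium it took the 4 genes with the smallest p of the AT2, lipid and AT1 lists, up to 2 rising and 2 falling genes past 0.05 of each other list described, and 5 rising and 5 falling genes of no list with the smallest p. For AT1-like cells, AT2-like cells and the interaction it took 5 and 5, and elsewhere 3 and 3; genes outside the lists had to have both KO libraries beyond both controls, which was not applied to the interaction. Genes without a symbol, among which Gm and Rik names and repeated identifiers were counted, and mitochondrial, ribosomal protein and hemoglobin genes were passed over except as list members. Some genes that the rule selected are not reported here. Sftpc, Ager, Pparg, Lpl, Ear2 and C1qa, and the list members shown as examples in single classes, were chosen after values or cluster tables had been seen, and Csf2 was chosen with its hypothesis.

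Alternatives were RLE size factors, library size scaling, DESeq2 1.42.0, no gene filter, each library left out in turn, the replicate number as a block, no doublet removal, a stricter cell filter (1000 genes, 10% mitochondrial UMIs), equal cell numbers, a marker gate for the epithelium, halved and doubled resolution, clustering without list genes, removal of genes with over 10 times more CPM in the control epithelium, an estimated correlation, fry and a denominator without immune and erythroid cells. Earlier classifications b, c and d, crossed replicate numbers, immune shares without unnamed cells, alveolar clusters alone, and the clustering alternatives for single classes were added after seeing the data. The test steps were tested on simulated data with 200 changed genes. These were drawn only from genes above a floor of expected counts, and the simulated spread between libraries followed the trend over all genes. The rates below therefore do not hold for genes at low counts or with a larger spread. Changes of 2-fold were recovered in 80% of cases in the epithelium, 95% in AT2-like, 92% in AT1-like, 74% in airway secretory-like, 88% in endothelial, 82% in mesenchymal and 77% in immune cells, and in 78% for the interaction. Figures were drawn with matplotlib 3.10.9.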

Results

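Whole fetal mouse lungs taken at embryonic day E18.5, shortly before birth, were profiled by droplet single-cell RNA-seq. There were 4 libraries, 2 labelled Control and 2 labelled PRDM3/16 KO, and each library pooled 2 lungs of one genotype. In the KO, Cre expressed from the Shh locus recombined conditional alleles of Prdm16 and of Mecom, the gene that encodes PRDM3; both are zinc finger proteins of the PR domain family that act on chromatin. Shh is expressed in the lung epithelium from early development, so the epithelium is the lineage in which recombination was directed. The matrices held 17407 and 2874 barcodes for Control 1 and Control 2, and 5791 and 5674 for KO 1 and KO 2. Total UMI counts were 160818268, 58276069, 75621791 and 88696368 in the same order. After filtering, 12458, 1947, 2707 and 2656 cells were kept, with median depths of 6317, 23141, 15684 and 17686.5 UMIs. Control 1 therefore held the most cells and the fewest UMIs per cell. The median hemoglobin share of a barcode's UMIs was 0.206% and 0.112% in the controls and 2.64% and 3.99% in the KO libraries. In every gene named below as changed between the groups, both KO libraries lay beyond both control libraries.

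Transcripts of the targeted genes were present in all 4 libraries. In summed epithelial cells, Prdm16 (ENSMUSG00000039410, mm10 chromosome 4, 154316125 to 154636873) fell from 19.7 ± 2.13 to 15.0 ± 1.17 CPM (SD, n = 2 per group), a log2 fold change of -0.39 with SE 0.12 (edgeR adjusted p = 0.0432). That call was lost without Control 2 and without KO 1, with log2 fold changes of -0.29 and -0.29, and also with DESeq2 at -0.39 and with library size scaling at -0.26. It was lost as well under 6 other choices of cells, at -0.37 to -0.20. Mecom (ENSMUSG00000027684, chromosome 3, 29951296 to 30548008) stood at 336 and 351 CPM, a log2 fold change of 0.07 (adjusted p = 0.779). Shh (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256), whose locus carries the Cre, stood at 55.6 and 60.0 CPM, a log2 fold change of 0.11 (adjusted p = 0.621). Counts of whole genes cannot show the loss of single exons, and the labels give neither the deleted exons nor the transcript end that was counted, so these values do not check the genotype labels.

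The main comparison asked which genes differ between KO and control epithelium. The surfactant programme of the alveolar type 2 (AT2) cell was lower in KO epithelium. Of 27 measured genes of the AT2 and surfactant list, 26 fell, both over all genes and adjusted over the list alone, and Slc27a2 did not pass (log2 fold change -0.48). Hc, which encodes complement C5, went from 607.6 to 9.72 CPM (log2 fold change -5.97). Chil1, a chitinase-like secreted protein, changed by -4.75, Sftpd, a surfactant collectin, by -3.61 and Lamp3, a lamellar body membrane protein, by -3.34. Sftpc, the AT2 surfactant protein, went from 111110 to 26687 CPM (-2.06, SE 0.27, adjusted p = 0.00103), a call lost without KO 1 at -1.93. The list had a median log2 fold change of -2.06 and an adjusted p = 4.74e-16 with the preset correlation, and an adjusted p = 0.53 with an estimated correlation. Genes of lipid and sterol synthesis, which supply surfactant lipid, fell in 31 of 40 cases and rose in 2, with 7 not passing; adjusted over the list alone, 32 fell and 3 rose. The desaturase Scd1 went from 1285 to 26.4 CPM (-5.60), and Insig1, a sensor of sterols, changed by -2.49, Gpam, the first acyltransferase of glycerolipid synthesis, by -2.48 and Fasn, the fatty acid synthase, by -2.43 (list median -0.72, adjusted p = 3.55e-08, and adjusted p = 0.58 with an estimated correlation). Members of the alveolar type 1 (AT1) list went both ways. Of 28 measured, 6 rose, 3 fell and 19 did not pass, and adjusted over the list alone 5 rose and 3 fell (median 0.10, adjusted p = 0.612, and adjusted p = 0.96 with an estimated correlation). The guidance cue Sema3a rose by 0.98 and the sodium channel subunit Scnn1g by 0.63, while the proteoglycan Spock2 changed by -0.68 and the AT1 surface glycoprotein Pdpn by -0.66; the calls for Spock2 and Pdpn were lost in alveolar clusters alone, at -0.20 and -0.23. Over all genes, 5708 of 15355 tested differed between the groups, 2786 higher and 2922 lower in KO. Scaling by library size alone gave 3224 higher and 1799 lower and moved the median over all genes to 0.13. The named genes of these 3 lists that passed have SEs of 0.10 to 0.16 apart from Sftpc.

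Genes typical of gut and neuroendocrine epithelium were higher in KO epithelium. In the gastrointestinal list, 10 of 15 measured genes rose, 2 fell and 3 did not pass, and adjusted over the list alone 11 rose and 2 fell. Measured genes are those past the count filter. They are 15 of 27 listed here, 9 of 13 in the neuroendocrine and tuft list and 8 of 11 in the basal and squamous list. A gene could pass the filter through the KO libraries alone, which can raise the share of rising genes and the medians of these lists. Gkn2, a gastrokine of the stomach lining, went from 1.17 to 51.5 CPM (log2 fold change 5.42), and Muc5ac, a gel-forming mucin, changed by 5.70. Gkn3 changed by -3.87 and the claudin Cldn2 by -1.66; Cldn2 passed only with all 4 libraries in, and stood at -2.23 to -1.24 with 1 left out. The gastrointestinal list had a median of 2.69 and an adjusted p = 0.00014, and an adjusted p = 0.57 with an estimated correlation. Among 9 neuroendocrine and tuft cell genes, 7 rose, 1 fell and 1 did not pass, with the same numbers adjusted over the list alone (median 4.70, adjusted p = 0.0225, and adjusted p = 0.84 with an estimated correlation). Calca, which encodes the neuropeptide CGRP, had 125 and 2 UMIs in the controls and 14119 and 11263 in the KO libraries, and the prohormone convertase Pcsk1 had 19, 0, 533 and 563; their log2 fold changes were 8.36 and 6.46, and 12.64 and 12.13 without Control 1. In alveolar clusters alone, which leave out neuroendocrine-like and airway secretory-like cells, the change of Calca was 3.01 and that of Muc5ac 3.67. Dclk1, a tuft cell kinase, changed by -2.45, and by -5.84 in alveolar clusters alone. The airway secretory list was divided, with 5 of 12 genes higher, 3 lower and 4 not passing, and 6 higher and 3 lower adjusted over the list alone (median 0.53, adjusted p = 0.457, and adjusted p = 0.96 with an estimated correlation). Its mucin Muc5b changed by 4.98 and the airway secretory protein Bpifa1 by 6.41, while haptoglobin, Hp, changed by -2.41, with -4.40 in alveolar clusters alone, and the antimicrobial lectin Reg3g had 215 and 430 UMIs in the controls and 8 and 0 in the KO libraries. Of 8 basal and squamous genes, 6 rose, 1 fell and 1 did not pass, also when adjusted over the list alone (median 3.99, adjusted p = 0.0652, and adjusted p = 0.84 with an estimated correlation). Keratin 4, Krt4, changed by 7.66 and Sfn, 14-3-3 sigma, by -0.93, and Trp63, the basal cell transcription factor, had 2 and 3 UMIs in the controls and 71 and 67 in the KO libraries. Proliferation genes rose in 24 of 30 cases, fell in none and did not pass in 6, with 25 higher adjusted over the list alone (median 0.73, adjusted p = 4.44e-07, and adjusted p = 0.53 with an estimated correlation). Rrm1, a ribonucleotide reductase subunit, changed by 1.43 and Mcm3, a replication helicase subunit, by 1.57. Within AT2-like cells the proliferation list was not called, with 6 of 30 higher and 3 lower (median -0.03, camera adjusted p = 0.753). Nor was it called within AT1-like cells, with 6 of 24 higher and 2 lower (median 0.53, camera adjusted p = 0.0991). Airway secretory-like cells, where it was called higher, are described below.

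Several response programmes were lower in KO epithelium. Glucocorticoid response genes, part of late lung maturation, fell in 11 of 15 cases and rose in 1, with 12 lower and 3 higher adjusted over the list alone; Klf15 changed by -2.48 and Errfi1 by -1.42 (list adjusted p = 0.013, and adjusted p = 0.58 with an estimated correlation). Pnmt, a methyltransferase of epinephrine synthesis, rose by 2.19, and passed only with all 4 libraries in, at 1.28 to 3.36 with 1 left out. TGF-beta and BMP targets fell in 9 of 15 cases and rose in 1, with 9 and 2 adjusted over the list alone; Pmepa1 changed by -1.44 and the inhibitor of differentiation Id4 by 1.52, which turned to -0.69 in alveolar clusters alone (list adjusted p = 0.0225, and adjusted p = 0.58 with an estimated correlation). WNT targets fell in 7 of 11 cases and rose in 1, also adjusted over the list alone; the feedback inhibitor Nkd1 changed by -2.35, Sp5 by -1.59 and the transcription factor Tcf7l2 by 1.66 (list adjusted p = 0.0291, and adjusted p = 0.58 with an estimated correlation). Interferon response genes fell in 8 of 20 cases and rose in 1, with 9 and 1 adjusted over the list alone; the ubiquitin-like modifier Isg15 changed by -2.59, its protease Usp18 by -1.51 and Ifi44 by 1.39 (list adjusted p = 0.00483, and adjusted p = 0.58 with an estimated correlation). Antigen presentation genes fell in 8 of 11 cases and rose in 2, also adjusted over the list alone. Cd74 and H2-Ab1, of class II, changed by -3.47 and -2.73, and B2m and H2-T23, of class I, by 1.46 and 0.84 (list adjusted p = 0.0148, and adjusted p = 0.58 with an estimated correlation). Lung epithelial transcription factors fell in 14 of 26 cases and rose in 4, also adjusted over the list alone; Stat3 changed by -1.69, the ETS factor Elf5 by -1.74 and the proximal airway factor Sox2 by 2.00, and Tfap2c had 3 and 0 UMIs in the controls and 40 and 30 in the KO libraries (list adjusted p = 0.0266, and adjusted p = 0.84 with an estimated correlation). Hypoxia and glycolysis genes fell in 9 of 21 cases and rose in 1, with 9 and 2 adjusted over the list alone; the collagen prolyl hydroxylases P4ha2 and P4ha1 changed by -1.75 and -1.21 and the enolase Eno1 by 0.59, a call lost without Control 1 at 0.56 (list adjusted p = 0.0441, and adjusted p = 0.84 with an estimated correlation). Unfolded protein and amino acid stress genes fell in 10 of 21 cases and rose in 2, also adjusted over the list alone (list adjusted p = 0.0313, and adjusted p = 0.58 with an estimated correlation). Herpud1 and Sesn2 changed by -1.28 and -1.52, and Phgdh, the first enzyme of serine synthesis, and the chaperone Sdf2l1 by 1.74 and 0.84. Within AT2-like cells 8 of 19 genes of this list fell and 6 rose (camera adjusted p = 0.875). Within AT1-like cells 7 of 19 fell and 5 rose (camera adjusted p = 0.727). None of the other lists of this paragraph was called within AT2-like cells (camera adjusted p = 0.0554 to 0.308), though more members fell than rose in each. Within AT1-like cells the glucocorticoid, interferon and hypoxia lists were called. The TGF-beta and BMP, WNT, antigen presentation and transcription factor lists were not (camera adjusted p = 0.0571 to 0.704). A changed mix of epithelial cells could also lower these sums.

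Among genes in no list, the smallest p-values for higher expression in KO epithelium belonged to Spink4, Ildr2, Guca2a, Dcpp1 and Dcpp3. Spink4, a serine protease inhibitor of goblet cells, changed by 6.02 and Ildr2, a membrane protein, by 5.07, and Guca2a, the gut hormone guanylin, went from 0.891 to 238 CPM. Dcpp1 had 1 and 0 UMIs in the controls and 986 and 857 in the KO libraries, and Dcpp3 had 3, 0, 1559 and 1918; these are near-identical paralogs, so the division between them is uncertain. The smallest p-values for lower expression belonged to Atp6v1c2, a proton pump subunit (-4.05), the potassium channel subunit Kcne2 (-5.11), Tinag (-4.49), the secreted resistin-like protein Retnla (-6.40) and the fatty acid binding protein Fabp12, with 3203 and 1512 UMIs in the controls and 2 and 4 in the KO libraries. All 10 had edgeR adjusted p-values of 3.32e-06 or below. Csf2, the growth factor GM-CSF, was chosen together with a hypothesis and went from 7.29 to 0.839 CPM (-3.09, SE 0.52, adjusted p = 0.00333).

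**Figure D1:**
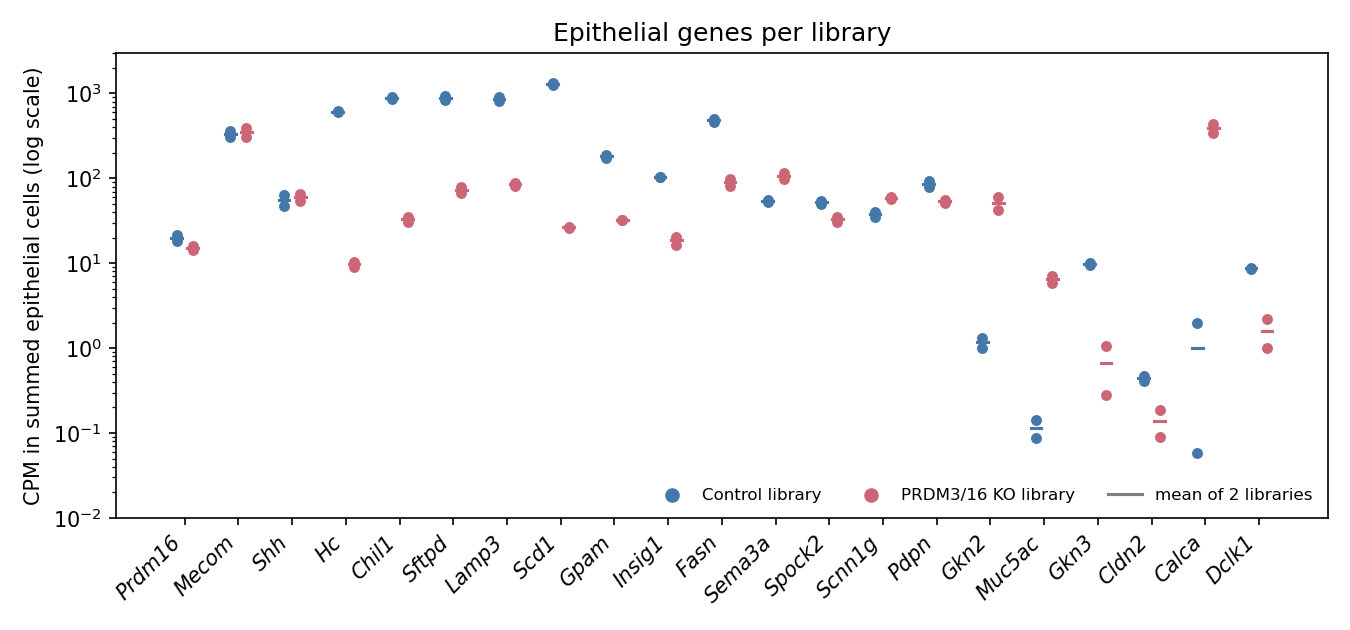
Expression of named genes in summed epithelial cells, as TMM-scaled CPM on a log axis with a point per library (blue, Control; red, PRDM3/16 KO; short lines, means of the 2 libraries of a group). AT2 and lipid genes such as Hc and Scd1 lie lower in both KO libraries, Gkn2 and Calca lie higher, and Mecom and Shh overlap between the groups.

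AT2-like cells of the KO had less of the AT2 programme and more of the AT1 programme than AT2-like cells of the control. Clusters with AT1 and AT2 markers together were left out of both classes. They held 813 and 132 control cells and 0 and 1 KO cells, and their effect on this comparison was not tested. Of 26 measured AT2 and surfactant genes, 22 fell, none rose and 4 did not pass, with 23 lower adjusted over the list alone. Examples are Chil1 (-3.45), the fatty acid binding protein Fabp5 (-2.39), Sftpd (-2.35) and the chemokine Cxcl15 (-2.29). The list had a median of -1.06 and an adjusted p = 3.03e-10, and an adjusted p = 0.65 with an estimated correlation. Of 27 AT1 genes, 23 rose, none fell and 4 did not pass, also adjusted over the list alone. S100a6 changed by 2.68, Sema3a by 2.47, the cytoskeletal regulator Rtkn2 by 2.28 and Scnn1g by 2.21 (median 1.14, adjusted p = 4.21e-08, and adjusted p = 0.79 with an estimated correlation). Ager, the AT1 receptor RAGE, went from 580.4 to 2387 CPM (2.04, adjusted p = 4.04e-07), and Sftpc changed by -1.01 (SE 0.28, adjusted p = 0.0124), a call lost without KO 1 at -1.001 and without KO 2 at -1.02. Lipid and sterol genes fell in 19 of 39 cases and rose in 3, also adjusted over the list alone (median -0.23, adjusted p = 0.00509, and adjusted p = 0.79 with an estimated correlation). Gastrointestinal genes rose in 3 of 5 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.0349, and adjusted p = 0.79 with an estimated correlation). Erythroid RNA, a marker of other cells, moved with this group, with 6 of 9 genes higher and none lower, and 6 and 2 adjusted over the list alone (median 1.94, adjusted p = 0.189, and adjusted p = 0.87 with an estimated correlation).

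Gkn2 (6.88), the keratinocyte secreted protein Dmkn (6.98), the acute phase protein Saa3 (6.21), Nup62cl (5.61) and the calcineurin inhibitor Rcan2 (4.57) had the smallest p-values among genes higher in KO AT2-like cells. Saa3 went from 29.0 to 2139 CPM. The lower genes were Hc (-4.95), Hp (-4.54), the protease inhibitor Serpine2 (-4.60), Tinag (-3.45) and Fabp12, with 2460 and 1142 UMIs in the controls and 1 and 3 in the KO libraries. Log2 fold changes of Prdm16, Mecom and Shh were -0.27 (adjusted p = 0.171), 0.34 (adjusted p = 0.074) and 0.23 (adjusted p = 0.21); without Control 1, Prdm16 passed at -0.40 and Mecom at 0.46, and without Control 2 Shh passed at 0.43. In all, 4516 of 12849 genes differed, 2179 higher and 2337 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The class held 3765, 601, 126 and 172 cells in Control 1, Control 2, KO 1 and KO 2. The cells came from different clusters in the 2 groups: KO cells lay in a cluster led by Saa3, Dmkn, Gkn2 and Lyz1, and control cells in clusters led by Retnla, Scd1, Hc, Cxcl15 and Lamp3. The class was large enough to test in 4 of 8 clusterings or classifications. Among these 4, classification d was an earlier naming of the main clusters and not another clustering. Lists past the threshold numbered 4, and 12 without Control 1, 3 without Control 2 and 6 without KO 1.

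AT1-like cells of the KO had less of the AT1 programme. Of 27 measured AT1 genes, 22 fell, none rose and 5 did not pass, also adjusted over the list alone. Pdpn changed by -1.77, Spock2 by -1.68, Pxdc1 by -1.64 and the basement membrane collagen Col4a4 by -1.38 (median -0.82, adjusted p = 1.27e-08, and adjusted p = 0.755 with an estimated correlation). Ager stood at 7284 and 6678 CPM (-0.13, adjusted p = 0.640). AT2 and surfactant genes went both ways, with 6 of 26 higher, 13 lower and 7 not passing, and 6 higher and 14 lower adjusted over the list alone (median -0.47, adjusted p = 0.174, and adjusted p = 0.94 with an estimated correlation). Sftpc rose by 0.77 (SE 0.20, adjusted p = 0.0048), a call lost without Control 2 at 0.51, without KO 1 at 0.64, with DESeq2 at 0.76 and with equal cell numbers at 0.19, and its direction turned under other clusterings, to -3.13 in the widest case. Interferon response genes fell in 13 of 20 cases and rose in 1, with 15 and 1 adjusted over the list alone (median -1.18, adjusted p = 2.57e-05, and adjusted p = 0.755 with an estimated correlation). Pan-immune markers, from other cells, moved with this group, with 3 of 6 lower and none higher, also adjusted over the list alone (median -0.97, adjusted p = 0.123, and adjusted p = 0.93 with an estimated correlation). Lower with an estimated-correlation p of 0.755 were also glucocorticoid response genes, with 10 of 14 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.000664), and immediate early genes, with 9 of 15 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0178). With an estimated-correlation p of 0.93, lipid and sterol genes fell in 21 of 38 cases and rose in 4, with 21 and 5 adjusted over the list alone (adjusted p = 0.0178). Hypoxia genes fell in 9 of 19 cases and rose in 2, with 10 and 2 adjusted over the list alone (adjusted p = 0.0335, and adjusted p = 0.93 with an estimated correlation). Epithelial ion and fluid transport genes fell in 7 of 14 cases and rose in 1, also adjusted over the list alone (adjusted p = 0.0297, and adjusted p = 0.93 with an estimated correlation).

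Dmkn, with 12 and 3 UMIs in control and 15550 and 15441 in KO AT1-like cells, and the cilium and flagellum protein Cfap57, with 0, 2, 2191 and 2185, were among the genes higher with the smallest p, with Nup62cl (6.74), the secreted protein Tafa4 (4.89) and the sialyltransferase St3gal4 (6.95). The lower genes were the caveolar protein Cavin4, with 788 and 329 UMIs in the controls and 2 and 4 in the KO libraries, Phgr1 (-4.63), the phospholipase Plb1 (-4.38), the phosphoglycerate mutase Pgam2 (-5.55) and the G protein subunit Gnb4 (-5.08). Prdm16, Mecom and Shh had log2 fold changes of -0.24 (adjusted p = 0.267), 0.35 (adjusted p = 0.0593) and -0.31 (adjusted p = 0.0951); without Control 1 all 3 passed, at -0.47, 0.53 and -0.59. By edgeR, 4269 of 12077 genes differed, 2084 higher and 2185 lower. KO cells (334 and 410) lay in a cluster led by Dmkn, Cfap57 and Tafa4, and control cells (1422 and 201) in clusters led by Aqp5, Akap5, Rtkn2 and Cavin2. Lists past the threshold numbered 7, and 13 without Control 2 and 11 without KO 1.

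The difference between the KO effects in AT1-like and AT2-like cells was tested directly. Clusters with AT1 and AT2 markers together, nearly all of them control cells, were left out here as well. Both lists also hold markers that named the classes, such as Ager and Sftpc. For these lists the test therefore cannot tell a different KO effect within cells from how cells were divided into classes. The effect on the AT1 list was more negative in AT1-like cells for 26 of 27 genes, also adjusted over the list alone, with a median difference of -1.99. For the AT2 and surfactant list, the effect was more positive in AT1-like cells for 18 of 26 genes and more negative for 2, with 20 and 2 adjusted over the list alone (median difference 0.81). Ager changed by 2.04 in AT2-like cells and stood at -0.13 in AT1-like cells, a difference of -2.17 (adjusted p = 2.17e-19). Sftpc had effects of -1.01 and 0.77, a difference of 1.80. Glul, glutamine synthetase, rose by 2.96 in AT1-like cells and stood at 0.0067 in AT2-like cells. By edgeR's interaction test 3474 of 12828 genes had different effects, 1775 with the more positive effect in AT1-like cells and 1699 with the more negative one; library size scaling gave 1193 and 2261. Prdm16 and Mecom had differences of 0.04 (adjusted p = 0.902) and 0.03 (adjusted p = 0.816), and Shh one of -0.52 (adjusted p = 0.000144).

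**Figure D2:**
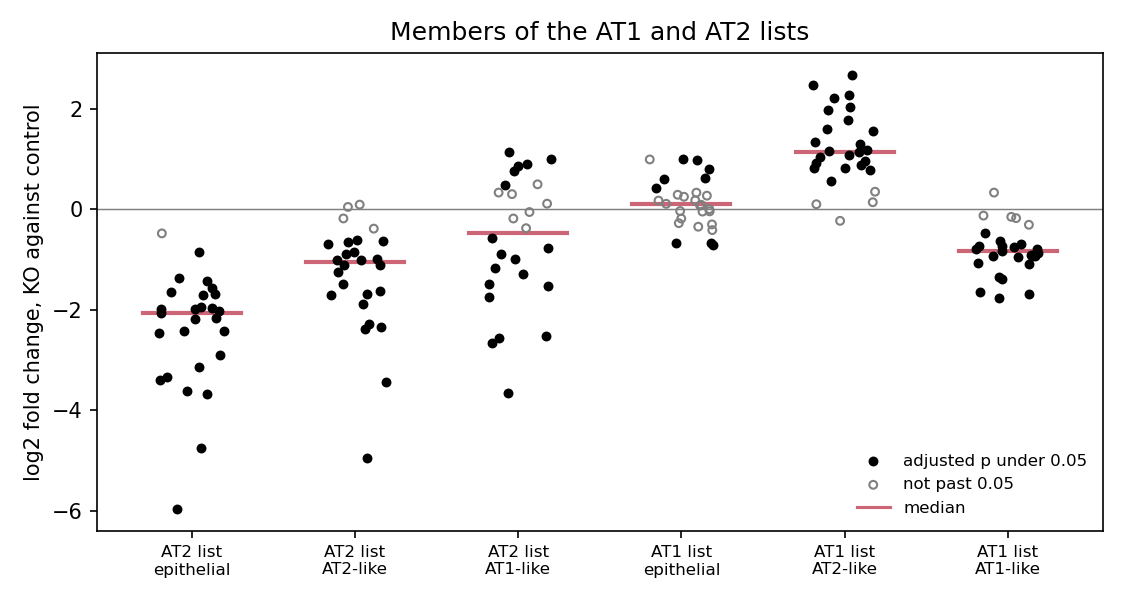
Log2 fold changes, KO over control, of each measured member of the AT2 and surfactant list and of the AT1 list in all epithelial, AT2-like and AT1-like cells (filled black, past an adjusted p of 0.05; open grey, not past it; red line, median). AT2 list medians are -2.06, -1.06 and -0.47, and AT1 list medians 0.10, 1.14 and -0.82, in that order.

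Airway secretory-like cells of the KO had fewer transcripts of club cell and of AT2 genes. Of 11 airway secretory genes, 7 fell, 3 rose and 1 did not pass, also adjusted over the list alone (median -1.44, adjusted p = 0.00645, and adjusted p = 0.46 with an estimated correlation). AT2 and surfactant genes fell in 24 of 26 cases and rose in none, also adjusted over the list alone (median -3.85, adjusted p = 1.3e-23, and adjusted p = 0.41 with an estimated correlation). Napsa, the protease that processes surfactant proteins, changed by -5.47 and the Notch-like protein Dlk1 by -5.48 (lost without doublet removal, at -3.06), and Scd1 had 343 and 273 UMIs in the controls and 2 and 0 in the KO libraries. Proliferation genes rose in 12 of 28 cases and fell in none, with 19 higher adjusted over the list alone (median 1.39, adjusted p = 7.22e-09, and adjusted p = 0.41 with an estimated correlation). AT1 genes rose in 11 of 25 cases and fell in 2, with 14 and 2 adjusted over the list alone (median 0.70, adjusted p = 0.000484, and adjusted p = 0.54 with an estimated correlation). The membrane protein Basp1 (6.15), the TAM receptor ligand Gas6 (4.41) and Dmkn (5.08) had the smallest p-values among higher genes. Extracellular matrix genes fell in 12 of 15 cases and rose in none, also adjusted over the list alone (adjusted p = 2.84e-08, and adjusted p = 0.41 with an estimated correlation). Pan-mesenchymal markers fell in 5 of 5 cases, also adjusted over the list alone (adjusted p = 0.000135, and adjusted p = 0.41 with an estimated correlation). Macrophage markers fell in 3 of 5 cases, with 5 lower adjusted over the list alone (median -1.67, adjusted p = 0.000642, and adjusted p = 0.46 with an estimated correlation). TGF-beta and BMP targets fell in 7 of 14 cases, with 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.00124, and adjusted p = 0.42 with an estimated correlation). Hypoxia genes fell in 7 of 18 cases, with 10 lower adjusted over the list alone (adjusted p = 0.000187, and adjusted p = 0.53 with an estimated correlation). Epithelial ion and fluid transport genes fell in 7 of 14 and rose in 2, with 8 and 2 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.57 with an estimated correlation). Log2 fold changes of Prdm16, Mecom and Shh were -0.41 (adjusted p = 0.47), -0.24 (adjusted p = 0.465) and -0.16 (adjusted p = 0.664). By edgeR, 1318 of 10338 genes differed, 568 higher and 750 lower; library size scaling gave 1016 and 501, with a median over all genes of 0.25. KO cells (83 and 66) lay in a cluster led by Scgb3a1, Upk3a and Psca, and control cells (111 and 25) in one led by Scgb1a1, Scgb3a2 and Hp. With the resolution halved, without list genes and under classification c, the class held KO cells almost alone. The comparison could not be made there and depends on the clustering.

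In endothelial cells, which lie outside the Shh lineage, few genes differed. Vwf, the von Willebrand factor, went from 112 to 224 CPM (log2 fold change 1.00, SE 0.13, edgeR adjusted p = 0.0188), Afap1l2 changed by 1.17 and the airway secretory gene Scgb3a1 by 2.44. The lower genes with the smallest p are abundant in AT2 cells: Cxcl15 (-4.43, adjusted p = 0.0122), Retnla (-7.33) and Hc, with 175 and 45 UMIs in the controls and 3 and 0 in the KO libraries. AT2 and surfactant genes fell in 9 of 26 cases and rose in none, with 20 lower adjusted over the list alone (median -2.25, adjusted p = 4.03e-16, and adjusted p = 0.86 with an estimated correlation). Surfactant RNA in these cells moved with this group: Sftpc stood at 2615 and 879.7 CPM, before TMM scaling, in control and at 415 and 288.8 CPM in KO endothelial cells. Interferon response genes fell in 3 of 21 cases, with 14 lower adjusted over the list alone (median -0.72, adjusted p = 4.66e-10, and adjusted p = 0.86 with an estimated correlation). Pan-mesenchymal markers fell in 2 of 8 cases, with 4 lower adjusted over the list alone (median -1.01, adjusted p = 0.0018, and adjusted p = 0.86 with an estimated correlation). Lists called with no gene past the threshold over all genes were proliferation genes, lower with 7 of 30 adjusted over the list alone (adjusted p = 7.93e-08), WNT targets, higher with 3 of 10 (adjusted p = 0.000376), and TGF-beta and BMP targets, higher with 1 of 15 (adjusted p = 0.0334). Each of these had an adjusted p = 0.86 with an estimated correlation. Prdm16, Mecom and Shh had log2 fold changes of 0.48 (adjusted p = 0.52), 0.14 (adjusted p = 0.694) and -0.70 (adjusted p = 0.617). Of 12627 genes, 33 differed, 13 higher and 20 lower; library size scaling moved the median over all genes to 0.11. The calls for Vwf, Afap1l2 and Scgb3a1 were lost with equal cell numbers, at 1.01, 1.19 and 2.21, and that of Afap1l2 also under classification d, an earlier one, at 1.27. The number was 143 without Control 1, 428 without Control 2, 170 without KO 1 and 204 without KO 2. Lists past the threshold numbered 6, and 13, 15, 12 and 10 in the same order.

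In mesenchymal cells, 3 secreted proteins led the higher genes: Aspn, a small leucine-rich proteoglycan of myofibroblasts, went from 80.6 to 194.7 CPM (log2 fold change 1.27, edgeR adjusted p = 0.00594), the chemokine Cxcl14 changed by 1.35 and the protease-like Prss35 by 1.19. These 3 calls were lost without Control 1, at 1.27, 1.30 and 1.10, and without doublet removal, at 1.29, 1.34 and 1.22, and that of Prss35 also with equal cell numbers, at 0.93. The lower genes were Cxcl15 (-5.58), the AT2 phosphate transporter Slc34a2 (-4.72) and Enpp2, the enzyme autotaxin (-2.60). Without doublet removal the calls for Cxcl15 and Slc34a2 were lost, at -5.13 and -4.61, and under classification b, an earlier one, those for Cxcl15, Slc34a2 and Prss35, at -4.95, -4.41 and 1.17. AT2 and surfactant genes fell in 11 of 26 cases and rose in none, with 23 lower adjusted over the list alone (median -2.37, adjusted p = 4.55e-25, and adjusted p = 0.78 with an estimated correlation). Sftpc stood at 2947 and 1828 CPM, before TMM scaling, in control and at 224 and 470.2 CPM in KO mesenchymal cells. Myofibroblast and smooth muscle genes were shifted higher, with 1 of 18 passing over all genes and 8 higher and 3 lower adjusted over the list alone (median 0.35, adjusted p = 0.0124, and adjusted p = 0.78 with an estimated correlation). Of the 14 lists called, 10 had no gene past the threshold over all genes, and each of these 10 had an adjusted p = 0.78 with an estimated correlation. Shifted lower were interferon response genes, with none of 18 adjusted over the list alone (median -0.74, adjusted p = 1.64e-06), and WNT targets, with 4 of 13 (adjusted p = 0.00055). Glucocorticoid response genes were shifted lower with 4 of 14 (adjusted p = 0.00445), alveolar fibroblast and lipofibroblast genes with 2 of 14 (adjusted p = 0.0112), and epithelial ion and fluid transport genes with 1 of 11 (adjusted p = 0.0393). Lung epithelial transcription factors were shifted lower with 5 of 21 lower and 1 higher adjusted over the list alone (adjusted p = 0.00055). Shifted higher were proliferation genes, with 1 of 30 adjusted over the list alone (adjusted p = 0.000183), Notch targets, with 5 of 9 (adjusted p = 0.000308), YAP and TEAD targets, with none of 14 (adjusted p = 0.00232), and extracellular matrix genes, with 3 of 24 (adjusted p = 0.0048). Airway secretory genes were shifted lower, with 1 of 8 higher over all genes and 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.0483, and adjusted p = 0.78 with an estimated correlation). Lipid and sterol genes were shifted higher, with 1 of 39 lower over all genes and 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.0483, and adjusted p = 0.85 with an estimated correlation). Prdm16 and Mecom had log2 fold changes of 0.73 (adjusted p = 0.606) and 0.13 (adjusted p = 0.776), and Shh, with 24, 5, 3 and 6 UMIs in the order used above, was below the count filter. Of 13094 genes, 25 differed, 7 higher and 18 lower, and the number was 7 without Control 1, 242 without KO 1 and 407 without KO 2.

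Immune cells of the KO had fewer transcripts of cell division genes. Proliferation genes fell in 29 of 30 cases, also adjusted over the list alone (median -1.18, adjusted p = 8.92e-12, and adjusted p = 0.935 with an estimated correlation). Macrophage markers went both ways, with 7 of 19 higher and 6 lower, also adjusted over the list alone (median 0.15, adjusted p = 0.652, and adjusted p = 0.935 with an estimated correlation). Pparg, the nuclear receptor of alveolar macrophage maturation, went from 101 to 21.1 CPM (-2.27, adjusted p = 0.000786), the lipoprotein lipase Lpl changed by -2.58 and the ribonuclease Ear2 by -1.76, while C1qa, a complement subunit of tissue macrophages, changed by 1.46 (adjusted p = 0.00196); these 4 were named after cluster tables had been seen. By the fixed rule, the iron exporter Slc40a1 (2.11) and Cyp11a1, the first enzyme of steroid synthesis (2.51), were among the higher genes with the smallest p, and Perp (-2.53), the neuropeptide galanin, Gal (-3.02) and Phgdh (-2.54) had the smallest p among lower genes. Lipid and sterol genes fell in 22 of 38 cases and rose in 1, with 25 and 1 adjusted over the list alone (median -0.63, adjusted p = 2.76e-07, and adjusted p = 0.935 with an estimated correlation). AT2 and surfactant genes fell in 17 of 26 cases and rose in 4, with 18 and 5 adjusted over the list alone (median -1.74, adjusted p = 0.00129, and adjusted p = 0.935 with an estimated correlation). Surfactant RNA in immune cells moved with this group, with Sftpc at 2232 and 841.5 CPM, before TMM scaling, in control and at 268.7 and 247.5 CPM in KO immune cells. Interferon response genes rose in 11 of 21 cases and fell in none, with 15 higher adjusted over the list alone (median 0.74, adjusted p = 0.00109, and adjusted p = 0.935 with an estimated correlation). Antigen presentation genes rose in 5 of 12 cases and fell in none, with 9 higher adjusted over the list alone (adjusted p = 0.00742, and adjusted p = 0.935 with an estimated correlation). Immediate early genes rose in 10 of 18 cases and fell in 3, with 13 and 3 adjusted over the list alone (adjusted p = 0.00617, and adjusted p = 0.935 with an estimated correlation). Pan-immune markers rose in 6 of 7 cases and fell in none, also adjusted over the list alone (adjusted p = 0.0094, and adjusted p = 0.935 with an estimated correlation).

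Of 11560 genes in immune cells, 3140 differed by edgeR, 1630 higher and 1510 lower, and library size scaling gave 1198 and 1898, with a median over all genes of -0.11. Without Control 1 the number was 0, with 3067 at an unadjusted p under 0.05, and without Control 2 it was 0, with 3759; it was 1292 without KO 1 and 2649 without KO 2. Leaving out either control thus ended the call of every gene named for immune cells, and 3137 and 3140 of the 3140 genes kept their direction without Control 1 and without Control 2. Lists past the threshold numbered 7, and 15 without Control 1. Mecom had a log2 fold change of -1.09 (adjusted p = 0.138), which was 0.02 without Control 1, and Prdm16 (12, 3, 2 and 8 UMIs) and Shh (17, 5, 4 and 8 UMIs) were below the count filter.

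The epithelium made up less of the kept KO cells, and the endothelium more. Epithelial cells were 51.2% ± 0.0384 of control and 26.4% ± 3.44 of KO cells (SD, n = 2 per group; edgeR adjusted p = 0.0155, exact permutation p = 0.333), and endothelial cells 15.4% ± 0.608 and 26.9% ± 0.798 (adjusted p = 0.0155, exact permutation p = 0.333). Megakaryocytes or platelets were 0.185% and 0.652% (adjusted p = 0.0155). Immune cells were 12.5% and 16.7% (adjusted p = 0.0776), mesenchymal cells 15.3% and 19.1% (adjusted p = 0.199) and erythroid cells 2.06% and 7.67% (adjusted p = 0.184). Clusters with markers of more than one compartment, kept out of all of these, were 1.42% and 1.29% of cells, and such clusters with erythroid RNA 1.91% and 1.29%. The smallest p that a two-sided exact permutation test can give with 2 libraries against 2 is 0.333. No share passed by edgeR without KO 1 (3 at an unadjusted p under 0.05), where the epithelial log2 ratio of -0.95 became -0.83, and without KO 2 the epithelial share alone passed. Without Control 1, and without Control 2, 6 of the shares passed. Tissue digestion, red cell lysis and the depth of each library can set such shares, so they describe the cells recovered and not the makeup of the lung.

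**Figure D3:**
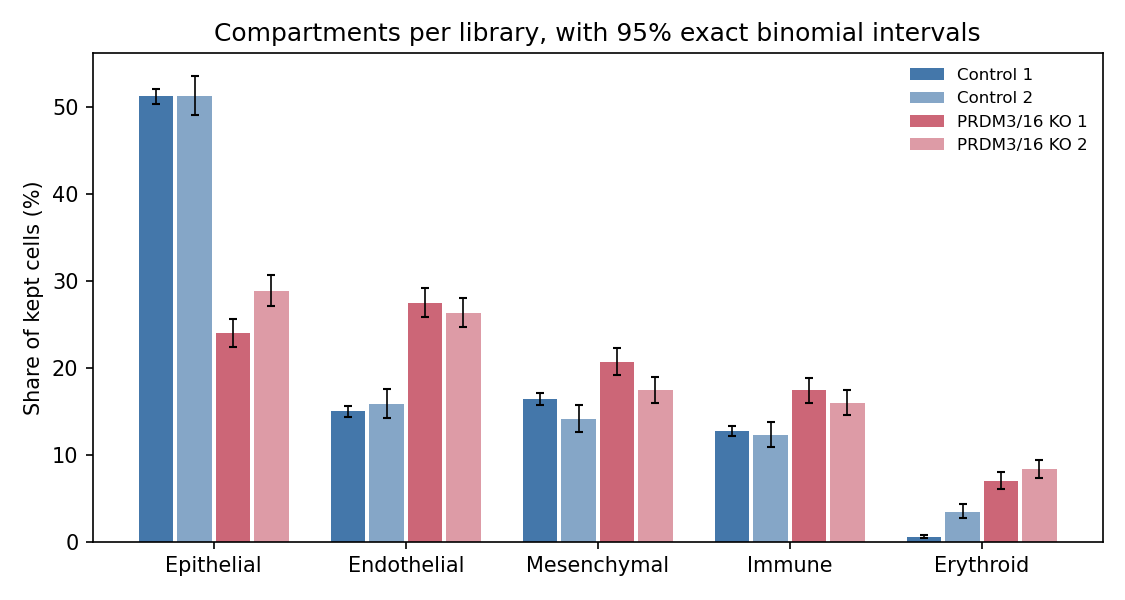
Shares of epithelial, endothelial, mesenchymal, immune and erythroid cells among all kept cells of each library, as bars in percent with 95% exact binomial intervals, which cover counting error only (blue, Control; red, PRDM3/16 KO). The epithelial share is 51.2% and 51.3% in the controls and 24.0% and 28.9% in the KO libraries.

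Within the epithelium, cluster sizes were compared in a clustering made without the genes of the AT1, AT2 and lipid lists. The clusters were still named from AT1 and AT2 markers, among them genes that differ between the groups. These shares are therefore not independent of those genes. AT1-like cells were then 21.7% and 19.7% of control and 45.7% and 45.1% of KO epithelial cells (log2 ratio 1.09, edgeR adjusted p = 1.37e-08). AT2-like cells were 59.6% and 59.6% in the controls and 24.7% and 29.8% in the KO libraries (-1.12, adjusted p = 7.21e-09). A cluster with AT1 and AT2 markers together was 12.0% and 13.5% in the controls and 0.153% and 0.130% in the KO libraries (-6.38, adjusted p = 3.61e-09). The AT2-like share of the KO depended on the clustering. Such cells numbered 1 of 626 and 4 of 755 in KO 1 and KO 2 with the resolution doubled, 3 of 668 and 4 of 791 without doublet removal, and 1 of 625 and 2 of 754, and 0 of 624 and 2 of 753, under earlier classifications. The log2 ratio of the AT2-like share was then -7.29, -7.17, -8.11 and -8.56. That of the AT1-like share was 0.78, 0.93, 0.60 and 1.08 in the same order. Many KO epithelial cells were left unnamed there, 218 and 300, 221 and 291, 199 and 274, and 154 and 200 in KO 1 and KO 2. In Control 1 and Control 2 the unnamed cells numbered 61 and 9, 313 and 33, 118 and 17, and 913 and 169. These AT2-like ratios therefore depend on the naming rule and do not show that such cells were absent. Shares of neuroendocrine-like and airway secretory-like cells are not compared, since that clustering kept the genes that define them, which differ between the groups.

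Among mesenchymal cells, myofibroblast-like cells were 11.6% of control and 3.75% of KO cells (edgeR adjusted p = 0.0141), and cells with markers of both adventitial and alveolar fibroblasts 3.66% and 9.79% (adjusted p = 0.0141). Cells with markers of both myofibroblasts and smooth muscle were 15.2% and 12.5% (adjusted p = 0.508), at 8.57% in KO 1 and 16.4% in KO 2. The myofibroblast-like share depends on how cells were divided between that class and this one. The alveolar fibroblast-like share was 49.8% and 41.4% (adjusted p = 0.508). Immune clusters left unnamed, led by Plet1, Lpl, Ear2 and Gal or by cell cycle genes, were 41.2% of control and 4.09% of KO immune cells (adjusted p = 6.82e-09). Each other immune share depends on them through the denominator. Among all immune cells, mast or basophil-like cells were 0.912% and 4.03% (adjusted p = 0.000353), neutrophil-like cells 11.4% and 27.2% (adjusted p = 0.000353) and monocyte-like cells 7.84% and 18.9% (adjusted p = 0.000827). Cells with markers of both macrophages and monocytes were 11.8% and 17.4% (adjusted p = 0.0269) and macrophage-like cells 19.2% and 17.6% (adjusted p = 0.805). Among the named immune cells alone, mast or basophil-like cells were 1.54% and 4.21% (adjusted p = 0.0177) and macrophage-like cells 32.7% and 18.4% (adjusted p = 0.0177). The direction for macrophage-like cells depended on the clustering, with log2 ratios of 0.78 to 0.99 among all immune cells under 5 other clusterings. The other 3 calls were lost there, with neutrophil-like cells at 19.5% and 28.3% (adjusted p = 0.103), monocyte-like cells at 13.4% and 19.7% (adjusted p = 0.205), and cells with both markers at 19.9% and 18.1% (adjusted p = 0.907). Among endothelial cells no class passed by edgeR and 1 had an unadjusted p under 0.05. General capillary-like cells were 4.2% and 13% of cells (adjusted p = 0.521) and arterial-like cells 10.8% and 14.3% (adjusted p = 0.278). Endothelial cells left unnamed were 58.2% of control and 46.0% of KO cells, so the named classes cover only a part of the endothelium. The general capillary-like share was 0.64% in Control 1 and 7.77% in Control 2, and its log2 ratio, 1.80 with all libraries, was 0.74 without Control 1 and 4.32 without Control 2. Without Control 1 the calls for the myofibroblast-like, both-fibroblast, mast or basophil-like and macrophage and monocyte cells were lost, at log2 ratios of -1.49, 1.04, 1.66 and 0.33. Without Control 2 the first 2 of these were lost, at -1.76 and 1.91, and without KO 1 the macrophage and monocyte call was lost, at 0.66. The myofibroblast-like call was lost with the resolution halved, at -0.74, or doubled, at -2.07, and under classification b, at -0.86. The macrophage and monocyte call was lost with a stricter cell filter, at 0.59, and turned to -0.07 with the resolution halved. The neutrophil-like call was lost under classification d, at 0.40, and the monocyte-like call under b and c, at 0.48 and 2.42. Of the shares of classes outside the epithelium, 7 passed with all libraries, and 3 without Control 1 and 12 without KO 2.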

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

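KO effects that differ between AT1-like and AT2-like cells by the interaction test are set out here as values, and the test was planned. In all, 3474 genes differed in this way. Positive differences, with the more positive effect in AT1-like cells, were 2.96 for Glul, 1.80 for Sftpc, 3.48 for the dipeptidase Dpp4, 2.81 for the kinase inhibitor Camk2n1 and 3.55 for the actin regulator Mtss1. Dpp4 changed by 4.29 in AT1-like and 0.80 in AT2-like cells, Camk2n1 by 1.07 and -1.72, and Mtss1 by 3.22 and -0.35. Negative differences were -2.17 for Ager, -2.50 for Tmem37, -3.27 for Psat1, an enzyme of serine synthesis, -3.90 for the membrane protein Emp1, -3.67 for the caveolar protein Cavin2 and -0.52 for Shh. Psat1 changed by -1.75 in AT1-like and 1.55 in AT2-like cells, Emp1 by -1.91 and 2.01, and Cavin2 by -2.05 and 1.63. Within each of these classes, KO and control cells lay in different clusters.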

How the results depend on the processing

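Crossed replicate numbers, classifications b, c and d, immune shares without unnamed cells, alveolar clusters alone, and halved and doubled resolution or clustering without list genes for single classes were chosen after seeing the data, and all other alternatives before. Between the alternatives that gave a value, the number of changed genes stayed within 1.5 times of 5708 in the epithelium (4169 to 6115 over the alternatives run, 4169 to 5380 with 1 library left out), of 4516 in AT2-like cells (3575 to 4708 with 1 library left out) and of 3474 for the interaction. A left-out library leaves its group with 1 library, which is then assumed to vary like the other group. AT2-like cells, and with them the interaction, gave no value without doublet removal, with the resolution doubled and under classifications b and c. Too few KO cells were so named there. Airway secretory-like cells gave none with the resolution halved, without list genes and under classification c, since too few control cells were so named. Control 1 and Control 2 held 1 and 0, 3 and 0, and 0 and 0 such cells in that order. KO 1 and KO 2 held 83 and 67, 82 and 69, and 86 and 72.

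Counts of changed genes moved further in these cases, and the cause was not tested except where given. With DESeq2 they were 2591 in AT1-like, 774 in airway secretory-like, 109 in mesenchymal and 2068 in immune cells. With equal cell numbers, which lowers the depth, they were 646 in airway secretory-like, 7 in endothelial, 11 in mesenchymal and 1780 in immune cells. With no gene filter they were 367 in endothelial and 612 in mesenchymal cells. Without doublet removal they were 20 in endothelial cells and 1 in mesenchymal cells, and without the genes more abundant in the control epithelium, which takes such genes out, 15 and 6. Mesenchymal cells had 3 under classification b, 13 under c and 16 with the resolution halved. With 1 library left out the ranges were 143 to 428 in endothelial, 7 to 407 in mesenchymal and 0 to 2649 in immune cells. The 0 came from edgeR without Control 1, with 3067 genes at an unadjusted p under 0.05, and without Control 2, with 3759.

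No list was called by camera with an estimated correlation. The numbers were 0 in the epithelium (3 lists at an unadjusted p under 0.05), 0 in AT2-like (1), 0 in AT1-like (0), 0 in airway secretory-like (4), 0 in endothelial (0), 0 in mesenchymal (0) and 0 in immune cells (1), against 13, 4, 7, 10, 6, 14 and 7 with the preset correlation. The test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 13 lists in the epithelium, 13 in AT2-like, 2 in AT1-like, 10 in airway secretory-like, 0 in endothelial (2 at an unadjusted p under 0.05), 0 in mesenchymal (5) and 3 in immune cells. With 1 library left out, camera with the preset correlation called 3 to 12 lists in AT2-like, 6 to 13 in AT1-like, 10 to 15 in endothelial and 7 to 15 in immune cells. Why these differ was not tested beyond the choice of the correlation.

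Shares past the threshold numbered 3 for compartments, and 7 with the stricter cell filter, 5 with the resolution halved and 0 to 6 with 1 library left out, the 0 being without KO 1, with 3 at an unadjusted p under 0.05 by edgeR. For classes outside the epithelium they numbered 7, and 4 with the resolution halved, 4 under classification d, 4 without unnamed immune cells and 3 to 12 with 1 library left out. The cause was not tested.

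With the replicate number as a replicate block, 113 endothelial and 5 mesenchymal genes passed, and 11 lists in AT2-like and 13 in endothelial cells; the other counts stayed within 1.5 times, with 5458 genes in the epithelium. The labels do not say that equal numbers share a litter or a day. Deviations of equally numbered libraries correlated at -0.0311 in the epithelium, -0.12 in endothelial, -0.227 in mesenchymal and -0.109 in immune cells. With the numbers crossed in the block, 213 endothelial and 490 mesenchymal genes passed.

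Among single values, 2949 kept their direction and their side of the threshold, 103 lost a call, 50 gained one and 59 changed sign. Sign changes of genes follow, with left-out libraries given as the lowest to the highest of the 4, and their cause was not tested. In the epithelium Mecom spanned -0.13 to 0.26 and Shh -0.070 to 0.33 with 1 library left out; Shh went to -0.00198 with equal cell numbers and Id4 to -0.69 in alveolar clusters alone. In AT1-like cells Shh went to 0.17 under classification b, Sftpc to -0.47 without doublet removal, -3.13 under b, -1.26 under c and -0.78 with the resolution doubled, and Ager to 0.54 under b, 0.065 under c, 0.011 with the resolution doubled and 0.0037 without list genes. In airway secretory-like cells Mecom went to 0.0013 and Shh to 0.067 with library size scaling, and Shh spanned -0.35 to 0.038 with 1 library left out. In endothelial cells Mecom went to -0.13 under d and Shh to 0.45 with equal cell numbers, and in immune cells Mecom spanned -1.63 to 0.019 with 1 library left out. For the interaction, Prdm16 went to -0.0048 with RLE, -0.080 with library size scaling and -0.048 without list genes and spanned -0.15 to 0.24, and Mecom went to -0.016, -0.089 and -0.039 and spanned -0.073 to 0.10.

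Sign changes of log2 share ratios, with the cause not tested, were as follows, with spans over the 4 left-out libraries. Mixed clusters spanned -0.40 to 0.17 and went to 0.15 without immune and erythroid cells and 0.66 under d, and those with erythroid RNA spanned -1.06 to 0.19. Clusters with airway secretory and ciliated markers spanned -0.15 to 0.89 and went to -0.094 without doublet removal, -0.45 with the resolution halved, -0.36 without list genes and -0.38 under c, and unnamed epithelial clusters went to -0.10 without list genes and -7.39 under d. Macrophage-like cells spanned -0.31 to 0.16 and went to 0.78 without doublet removal, 0.95 with the resolution halved, 0.84 with it doubled, 0.99 under b and 0.78 under c, and macrophage and monocyte clusters to -0.068 with the resolution halved and -0.030 without unnamed immune cells, where B-like cells went to -0.25. Spans were -0.32 to 0.24 for aerocyte capillary-like, -0.54 to 1.45 for lymphatic-like, -4.34 to 2.86 for mesothelial-like, -0.76 to 0.18 for myofibroblast and smooth muscle, -0.57 to 0.50 for dendritic-like and -0.18 to 1.37 for T or innate lymphoid-like cells. Classes of few cells, such as 4, 2, 11 and 0 mesothelial-like cells per library, are limited by counting.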

Other observations

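Further gene groups of the epithelium went both ways or had few genes past the threshold. Genes of the transitional alveolar state, seen in alveolar cells that change type, rose in 8 of 15 cases, fell in 4 and did not pass in 3, with the same numbers adjusted over the list alone (median log2 fold change 0.52, limma camera adjusted p = 0.327, and adjusted p = 0.84 with an estimated correlation). In AT2-like cells 9 of 14 rose and 4 fell, also adjusted over the list alone (median 0.84, adjusted p = 0.159, and adjusted p = 0.79 with an estimated correlation), and in AT1-like cells 4 of 15 rose and 7 fell, with 4 and 8 adjusted over the list alone (median -0.35, adjusted p = 0.264, and adjusted p = 0.93 with an estimated correlation). Distal tip progenitor genes rose in 4 of 15 cases and fell in 7, also adjusted over the list alone (median -0.09, adjusted p = 0.612, and adjusted p = 0.96 with an estimated correlation). Genes of epithelial ligands fell in 8 of 20 cases and rose in 3, also adjusted over the list alone (adjusted p = 0.366, and adjusted p = 0.96 with an estimated correlation). Notch targets rose in 3 of 10 cases and fell in 2, with 4 and 2 adjusted over the list alone (adjusted p = 0.596, and adjusted p = 0.96 with an estimated correlation), and ciliated cell genes rose in 1 of 13 and fell in none, with none adjusted over the list alone (adjusted p = 0.931, and adjusted p = 0.99 with an estimated correlation).

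Of the tests below, the one for fewer AT2-like cells was chosen only after its result had been seen, and the others before. For the lower AT2 and surfactant genes in KO epithelium, the shallower sequencing of Control 1 is argued against, since the list median was -2.07 (95% bootstrap interval over its genes -2.58 to -1.83) without that library. A different amount of free surfactant RNA is argued against as well, since the group difference in the list's summed CPM was 55.4 times larger in the epithelium than in endothelial cells. For fewer AT2-like cells, each with a control level of these genes, the test cannot decide. The list median within AT2-like cells was -1.06. Its interval of -1.62 to -0.785 lies below the -0.5 to 0.5 that this needs, though not wholly under the -1 also set as a bound. That interval covers the list's genes, and not the spread between libraries or the naming of cells. KO and control AT2-like cells lay in different clusters, and the class was named by members of this list. In 4 of 8 clusterings or classifications too few KO cells were so named to test. The other 3 with enough such KO cells gave -1.29 to -1.06, and classification d among them used the main clusters. A lower share of these cells, as the whole or a part of the cause, stays open. Loss of PRDM3 and PRDM16 in the epithelium remains an open biological explanation that no other genotype here can test.

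Lower genes in KO endothelial and mesenchymal cells may come from RNA of epithelial cells in the droplets. Of the 18 lower mesenchymal genes, 14, or 77.8% (exact 95% interval 52.4% to 93.6%), had over 10 times more CPM in the control epithelium than in mesenchyme, which is what this explanation needs. Of the 20 lower endothelial genes, 14, or 70%, did, with an interval of 45.7% to 88.1% that reaches below the bound set in advance, so in the endothelium this RNA and a change in the cells cannot be told apart. Without such genes 6 mesenchymal and 15 endothelial genes were called, of which 6 and 14 were also called with them. A response of these cells to the altered epithelium was not tested.

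Lower genes in KO immune cells are not explained by epithelial RNA, since 41 of 1510, or 2.72% (exact 95% interval 1.96% to 3.67%), met the same criterion. One hypothesis is that less Csf2 from the KO epithelium, a growth factor that alveolar macrophages need to mature, could lower genes such as Pparg and Lpl. Csf2 in the epithelium had a log2 fold change of -3.09, which is what the hypothesis needs, though this is a single gene at low counts. Its interval of -4.14 to -2.05 was built from the SE of 0.52 and is not an exact one. The support is weak, since 2922 of 15355 epithelial genes were lower in KO. A changed mix of epithelial cells could also lower Csf2 in the sum. A change in the makeup of the immune cells stays open and was not tested within a class, and the share of the unnamed clusters led by Plet1, Lpl, Ear2 and Gal or by cell cycle genes went from 41.2% to 4.09%.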
